A study of Mus musculus with 12 samples.

How the data were processed

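Femur marrow cells of 12-week-old male C57BL/6J mice were cultured for 48 hours with saline, with BMP-2 at 200 ng/ml or with TPO at 100 ng/ml, per the labels' protocols. Each of the 12 samples was hybridised in Cy5 to its own Agilent 2-colour mouse array, against a universal reference RNA from 11 mouse cell lines in Cy3, per the labels. There were 4 arrays per group and no dye swap, so each ratio is the marrow sample over the reference. The arrays were printed 4 to a slide. Slide 1 held saline 1, saline 4, BMP-2 1 and TPO 1, slide 2 held saline 2, BMP-2 2, BMP-2 4 and TPO 2, and slide 3 held saline 3, BMP-2 3, TPO 3 and TPO 4. The labels do not say whether the replicates are separate mice, separate cultures or parts of 1 pool, so the p-values measure only the spread between these samples.

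The deposited files are scanner output. The authors' spot values are the median pixel intensity of each spot and of its local background in both channels, not normalized, per the file headers. The spot quality flags (above background, saturated, outlier) take the values 0 and 1, per the file headers. A further deposited column gives the log10 of Cy5 over Cy3 after the software's own background subtraction and dye normalization, per the file headers. The software was Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes. The authors' series value table holds the same log10 ratio: it differed from the scanner column by at most 0.005 on every array, and each of its columns had a median of 0. Its scale, centring and direction are therefore known from this match.

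The median spot intensity took the place of the mean intensity, which the files do not hold; this substitution was foreseen before the data were examined. Background was corrected with normexp and an offset of 50, and the log2 ratios were normalized within each array by loess, in limma 3.58.1 under R 4.3.3 with the data.table package, version 1.17.8. Control spots and outlier spots (121 to 487 per array) were left out, and spots of 1 probe were averaged. No tested Cy5 spot was saturated (0 on each array). Of 41174 probes, 27816 were named through a match of their accession to the RefSeq gene table of assembly GRCm38.p6, which gave 18952 genes, and 13358 stayed unnamed. The files' own settings refer to another assembly, so no coordinates are given. A probe was tested if it was well above background in Cy5 on at least 4 of the 12 arrays, which left 24772 probes and 13564 named genes.

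A gene was represented by its brightest tested probe over all arrays, and 4614 genes had several tested probes. Among the genes with several probes that changed (2 for BMP-2 against saline, 133 for TPO against saline and 275 for TPO against BMP-2), 0, 3 and 62 had a probe of the opposite sign, of which 0 in each comparison passed the test, and 1, 83 and 194 had a probe that did not pass. A further 0, 24 and 137 genes passed only by another probe.

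Each of the 3 comparisons was fitted with limma's lmFit and eBayes on all 12 arrays with 1 mean per group, and p-values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. Fold changes are given as log2 differences with the standard error of the fit (SE) over n = 4 arrays per group. Gene lists of pathways and of cell type markers, 29 in all and fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the lists of a comparison. They were tested again with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. Where all probes of a gene were not well above background on all arrays of a group, the difference is written as "at least N-fold": the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes above background and the probe's own signal, taken per channel after loess and Aquantile normalization and open to dye bias without dye swaps.

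The rule for naming genes was set before the data were examined. Of the genes past the threshold whose arrays did not overlap between the groups and which were above background on all 4 arrays of a group, it takes the 12 largest folds in each direction. Where fewer than 10 genes passed, it takes the 10 genes with the smallest p. From each list it takes up to 4 members with the smallest adjusted p, and it always takes Mpl, Pf4, Itga2b, Gata1, Thpo, Bmp2, Id1, Id2, Id3, Smad6, Smad7, Socs3, Cish, Runx2, Sp7, Alpl, Bglap, Col1a1 and Spp1. Over the 3 comparisons this gave 416 gene results, of which 158 were followed through every alternative. Which of the 416 to follow was decided after their values had been seen.

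The alternatives were no background correction, the software's log ratio, median centring in place of loess, Aquantile normalization between arrays, the Cy5 signal alone, 2 other filters on dim probes, slide or replicate number as a block, only the groups compared, an intensity trend, array weights, the series value table, the mean over a gene's probes and leaving out each array in turn. Leaving out the 4 arrays of slide 1, and slide as a block together with array weights, were added after the data were seen, as were most alternatives for the shared genes. Without slide 1 the saline arrays left are saline 2 and saline 3. A call lost there can reflect fewer arrays as well as slide 1. The fitting steps were tested on simulated data for TPO against saline with 13564 genes, of which 50 were changed at each of 4 sizes: at log2 changes of 0.5, 1, 2 and 3 the fit recovered 34%, 92%, 100% and 100%, with 7 false calls. With a simulated slide effect of SD 0.3, the fit without a slide term recovered 0%, 44%, 98% and 98% with 0 false calls, and the fit with slide as a block 44%, 94%, 98% and 100% with 7. A simulated list shift of 0.5 came back as 0.49, and 0 of 25 unshifted lists passed. The simulated genes were drawn independently of each other, whereas the megakaryocyte list had an estimated correlation of 0.51 on the arrays. The simulation therefore does not show how often lists of correlated genes pass falsely. The number of arrays limits the precision of every value. The 12 arrays were scanned on 1 day, per the file headers, so the scan day makes no batch.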

Results

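Gene expression was measured in mouse femur marrow cells after 48 hours in culture with saline, with bone morphogenetic protein 2 (BMP-2, which drives bone formation) or with thrombopoietin (TPO, the growth factor of the platelet-forming megakaryocyte), in 4 samples per treatment. The series title is about thrombopoietic agents as inducers of bone in bone healing. The Cy5 channel, which held the marrow RNA, was well above background for 37.4% to 67.7% of probes per array, with a median spot signal of 73 to 119 intensity units, and the log2 ratios of any pair of arrays correlated at 0.882 to 0.989 across probes. The arrays of slide 1 (saline 1, saline 4, BMP-2 1 and TPO 1) stood apart from the other 8 on the first principal component, which held 41.0% of the variance, while TPO separated from both other groups on the second, with 24.8%. BMP-2 4 lay far out on the other side of the first (33.7, next array 12.8), had the lowest SD of log2 ratios (0.859) and the lowest correlation with the authors' value table (0.879). Without it the genes changed were 7 for BMP-2 against saline and 474 for TPO against BMP-2, in place of 5 and 753. Relative to slides 2 and 3, the genes of slide 1 differed by a median of 0.16 in log2 size, with a median shift of 0.57 for megakaryocyte and platelet genes, 0.56 for mast cell, basophil and eosinophil genes and 0.49 for neutrophil genes. Values within slides are therefore given beside those over all arrays.

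**Figure D1:**
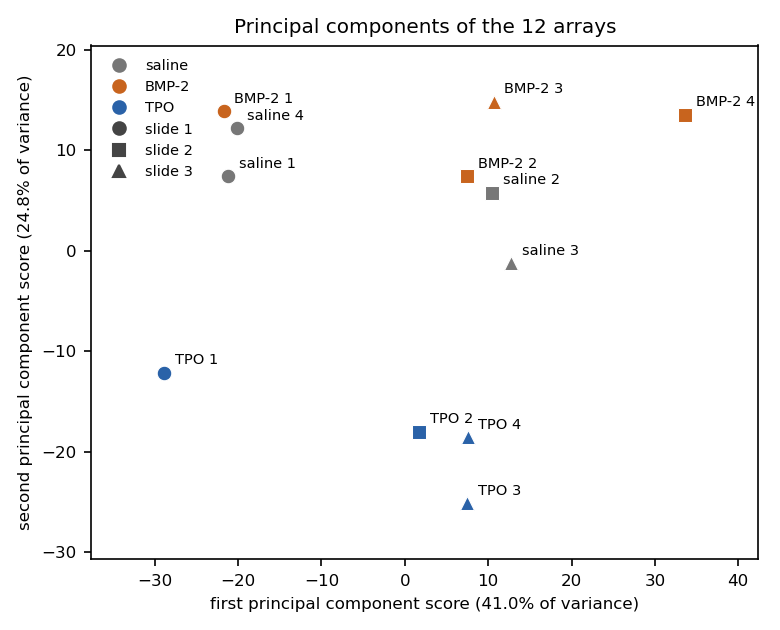
Scores of the 12 arrays on the first principal component (x axis, 41.0% of the variance) and the second (y axis, 24.8%), computed from log2 ratios of sample over reference. Colour gives the treatment and the symbol the slide; the 4 arrays of slide 1 lie to the left, BMP-2 4 lies far to the right and the 4 TPO arrays lie low.

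The comparison of BMP-2 with saline asks what the bone growth factor did to marrow cells. Alpl, the tissue-nonspecific alkaline phosphatase that osteoblasts use to mineralise bone, rose most, by 1.84 on the log2 scale (SE 0.149, n = 4 per group, a 3.58-fold rise, adjusted p = 0.000520), from a mean log2 ratio of 0.14 ± 0.32 (SD) with saline to 1.98 ± 0.21 with BMP-2. Whrn, which encodes the scaffold protein whirlin, rose by 0.85 (SE 0.0883, adjusted p = 0.00468), and Dynap, a dynactin-associated membrane protein, rose by 0.83 (SE 0.100, adjusted p = 0.0146). Ptgs2, the inducible cyclooxygenase that makes prostaglandins, rose by 0.76 (SE 0.0929, adjusted p = 0.0146), and Serpinb2, an inhibitor of plasminogen activators, rose by 0.98 (SE 0.137, adjusted p = 0.0372). These were the 5 genes that passed in limma, of 13564 tested. None fell (0), although 727 genes were lower and 1017 higher at an unadjusted p under 0.05. The 5 genes lay higher with BMP-2 on each of the 3 slides: Alpl by 1.65, 2.07 and 2.22, Whrn by 0.65, 0.99 and 0.95, Dynap by 1.13, 0.67 and 0.71, Ptgs2 by 0.82, 0.73 and 0.59, and Serpinb2 by 1.00, 0.64 and 1.38. They were picked on these same arrays, so this agreement largely follows from the choice and is no separate test.

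Further genes with small p-values did not pass. Among them were Fmod, a collagen-binding matrix proteoglycan (1.11, SE 0.175, adjusted p = 0.0840), Serpinf1, which encodes a factor needed for bone mineral (0.55, adjusted p = 0.0839), and the homeobox gene Dlx2 (0.73, adjusted p = 0.0873). Anxa8 (-0.48) and Klhl30 (-0.89) leaned the other way, each with an adjusted p of 0.0955. With slide as a block, 8 genes rose and 1 fell: Fmod then passed (adjusted p = 0.0264), as did Serpinf1 (0.0431) and Klhl30 (0.0271). With the Cy5 signal alone Fmod (1.03) and Klhl30 (-0.89) also passed, each with an adjusted p of 0.0162. The bone genes fixed beforehand other than Alpl did not pass over all arrays without a block. Sp7, the transcription factor osterix, lay at 0.83 (SE 0.433, adjusted p = 0.413), but passed with the Cy5 signal alone (1.16, adjusted p = 0.00727). Sp7 also passed with slide as a block and array weights (1.08, adjusted p = 0.00163). Bglap, osteocalcin, lay at 0.45 (adjusted p = 0.299), Col1a1 at 0.28, Spp1 at 0.22 and Runx2 at 0.12. The direct targets of BMP signalling did not pass either, where Smad6 lay at 0.41, Smad7 at 0.39, Id1 at 0.20, Id2 at 0.14 and Id3 at -0.43, with adjusted p from 0.246 for Smad7 to 0.508 for Id2. Bmp2 itself lay at -0.10. The megakaryocyte genes Pf4 (0.25), Mpl (0.08), Gata1 (0.01) and Itga2b (-0.55), the TPO gene Thpo (0.10) and the cytokine-response genes Cish (0.22) and Socs3 (-0.09) did not pass either.

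None of the 29 gene lists passed in camera (8 at an unadjusted p under 0.05; 0 with an estimated correlation and 0 with fry). Neutrophil genes (median -0.20), osteoblast genes (0.13), interferon genes (0.19) and cholesterol synthesis genes (-0.07) came nearest, each with an adjusted p of 0.0571. The neutrophil median turned to 0.11 with the Cy5 signal alone. Relative to the median of all genes, which median centring moved to 0.49, the neutrophil and cholesterol medians were -0.13 and -0.0023 there. Of 17 osteoblast genes tested, 1 rose and 16 did not pass, and the count was also 1 adjusted over the list alone; within slides their median was 0.16, 0.14 and 0.34. With slide as a block the osteoblast list passed upward (median 0.14), and the collagen (-0.10) and proliferation (-0.08) lists downward, each with an adjusted p of 0.0185 (adjusted p = 0.890 with an estimated correlation for the osteoblast list, and 0 lists passing). Over all arrays the collagen and proliferation medians were -0.11 and -0.09 relative to the median of all genes, and 0.0088 and 0.06 with median centring. The neutrophil median turned from -0.09 and -0.25 on slides 1 and 2 to 0.18 on slide 3. The median, mean and test differed in sign for the hypoxia (0.03, 0.01 and downward), inflammatory (0.00, 0.04 and downward) and BMP target lists (0.10, 0.00 and downward).

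The count of 5 rests on few arrays. Without saline 1, saline 4 or BMP-2 3 it was 2, and without the 4 arrays of slide 1 it was 1. Dynap lost its call without saline 1, saline 4 or BMP-2 3 (adjusted p 0.0747 to 0.0868), Ptgs2 without those or BMP-2 2 (0.0674 to 0.0868) and Serpinb2 without any of 10 of the 12 arrays (0.0633 to 0.199). Alpl kept its call under the 27 alternatives that tested it, which leaves out the filter on both channels. The software's log ratio ended the calls of Dynap (2.04, adjusted p = 0.131), Ptgs2 (0.99, 0.0809) and Serpinb2 (0.59, 0.143), and the Cy5 signal alone those of Dynap (0.64, 0.413), Ptgs2 (0.77, 0.206) and Whrn (0.83, 0.109). Dynap (0.0821) and Serpinb2 (0.333) also lost theirs with only the groups compared, and Serpinb2 (0.0510) with no filter on dim probes. Without slide 1 Whrn lay at 0.97 (0.0640), Dynap at 0.67 (0.299), Ptgs2 at 0.68 (0.277) and Serpinb2 at 0.98 (0.338). With the software's log ratio 10 genes were higher and 4 lower, and with the Cy5 signal alone 4 were higher and 1 lower. Median centring left 1 gene.

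**Figure D2:**
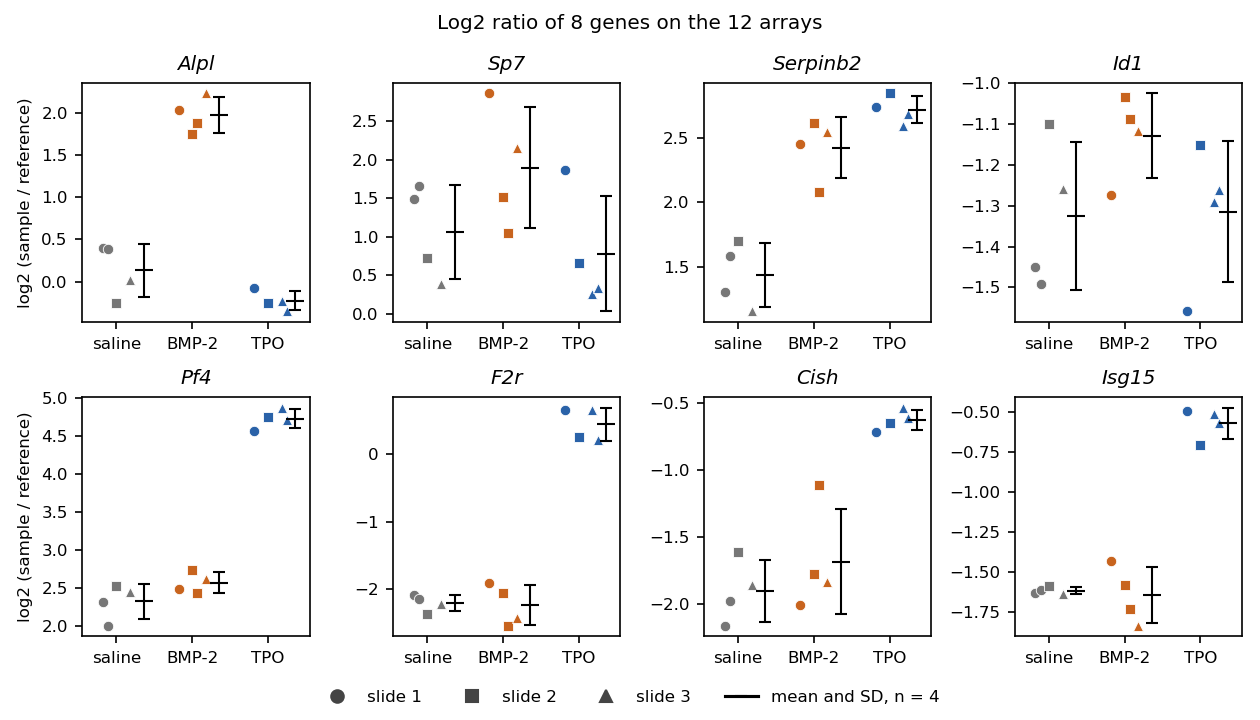
Log2 ratio of sample over reference (y axis) on each array for 8 genes, by treatment (x axis); symbols give the slide, and bars give the mean and SD of the 4 arrays of a group. All 4 BMP-2 arrays lie above all others for Alpl, and all 4 TPO arrays lie above all others for Pf4, F2r, Cish and Isg15, while the groups overlap for Sp7 and Id1.

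The comparison of TPO with saline asks what the platelet growth factor did to the same cells. Among genes of megakaryocytes and platelets, Pf4, the platelet chemokine PF4, rose by 2.40 on the log2 scale (SE 0.117, n = 4 per group, 5.28-fold, adjusted p = 1.79e-07), and F2r, a thrombin receptor, by 2.65 (SE 0.151, 6.25-fold, adjusted p = 5.09e-07). The largest change was in Col18a1, the collagen that endostatin is cut from, which rose 7.0-fold (2.81, SE 0.161, adjusted p = 5.09e-07). Flt1, a receptor for vascular endothelial growth factor, rose by 2.72 (SE 0.150), and Ehd3, an endosome trafficking protein, by 2.60 (SE 0.0871). In all, 386 genes rose and 18 fell, and 151 of those that rose and 0 of those that fell changed more than 2-fold (932 were higher and 611 lower at an unadjusted p under 0.05 in limma). A slide block gave 571 that rose and 59 that fell, 403 of the 404 genes being called in both fits. Of the 404, 401 (99.3%) differed in the same direction on all 3 slides, against 40.5% of all genes. The 404 were picked on these same arrays, so this agreement largely follows from the choice and is no separate test.

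Of 33 megakaryocyte and platelet genes tested, 10 rose, 23 did not pass and all 33 lay higher; 27 rose adjusted over the list alone. Their median was 0.96 (camera adjusted p = 5.96e-29; adjusted p = 0.0660 with an estimated correlation), and within slides it was 1.06, 1.23 and 1.35 (1.14 with slide as a block; adjusted p = 0.0975 with an estimated correlation). It was 0.58 with the software's log ratio and 1.71 with the Cy5 signal alone. Zfpm1, the GATA cofactor FOG1, rose by 1.70 (SE 0.102), Cavin2, a caveolar protein of platelets, by 1.65 (SE 0.101), and Rab27b, which moves platelet granules, by 2.11 (SE 0.279). Thbs1, thrombospondin, rose by 1.02 (SE 0.147) and Gata1, the master regulator of megakaryocytes and red cells, by 0.92 (SE 0.195, adjusted p = 0.0241). Gata1 lost its call without any of 7 of the 12 arrays, with adjusted p from 0.0509 to 0.0856 and log2 changes from 0.81 to 0.96, and with the software's log ratio (0.39, adjusted p = 0.482); Thbs1 lost its call with the mean over a gene's probes (0.88, 0.0770). Mpl, the TPO receptor, lay at 0.83 (SE 0.251, adjusted p = 0.170), and Itga2b, the platelet integrin, at 0.96 (SE 0.379, adjusted p = 0.410). With slide as a block Mpl passed (0.97, adjusted p = 0.00277) and Itga2b did not (adjusted p = 0.0890). Both passed with the Cy5 signal alone (Mpl 1.75, adjusted p = 7.82e-07, and Itga2b 1.41, adjusted p = 0.0104). Mpl also passed without the 4 arrays of slide 1 (1.21, adjusted p = 0.0118), and Itga2b with slide as a block and array weights (1.25, adjusted p = 0.00152). Thpo lay at -0.04. Outside the lists, the genes with the largest rises also included Clca3a1 (2.49, SE 0.348), the glutathione transferase Gsta1 (2.40, SE 0.212), the blood cell regulator Hemgn (2.28, SE 0.314), the myosin light chain kinase Mylk (2.14, SE 0.0792), the tubulin Tuba8 (2.14, SE 0.121) and Slc35d3, a platelet dense granule gene (2.12, SE 0.301). Hemgn lost its call with the software's log ratio (2.92, adjusted p = 0.195).

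Of 18 TPO and JAK-STAT target genes, 7 rose and 11 did not pass (9 rose adjusted over the list alone), with a median of 0.25 and adjusted p = 4.67e-07. This was the list that also passed with an estimated correlation (adjusted p = 0.0440), but not with slide as a block as well (adjusted p = 0.0975 with an estimated correlation). Cish, a feedback inhibitor of STAT5 signalling, rose by 1.28 (SE 0.171), the cyclins Ccnd3 and Ccnd2 by 0.78 (SE 0.0834) and 0.68 (SE 0.0885), and the kinase Pim1 by 0.68 (SE 0.0953). All 4 lost their calls with median centring (Cish 1.32, adjusted p = 0.192; Ccnd3 0.97, 0.183; Ccnd2 0.87, 0.744; Pim1 0.77, 0.363). Socs3 lay at 0.35 (adjusted p = 0.0539), and passed with slide as a block (adjusted p = 0.0323). Within slides the list's median was 0.32, 0.35 and 0.24 (0.31 with slide as a block).

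A further 6 lists passed upward. Of 19 interferon response genes 2 rose (7 adjusted over the list alone), Isg15 by 1.04 (SE 0.0912) and Rsad2 by 0.90 (SE 0.157). The list's median was 0.31 (adjusted p = 5.54e-08; adjusted p = 0.0660 with an estimated correlation), and 0.49, 0.17 and 0.17 within slides. Of 18 cholesterol synthesis genes 3 rose (8 adjusted over the list alone), among them Idi1 by 0.88 (SE 0.0861), Dhcr24 by 0.82 (SE 0.103) and Stard4 by 0.57 (SE 0.127), the last a sterol carrier. The median was 0.23 (adjusted p = 7.50e-07; adjusted p = 0.0623 with an estimated correlation), and 0.18, 0.25 and 0.29 within slides. Of 17 stem and progenitor genes 3 rose (7 adjusted over the list alone), among them Slamf1 by 2.05 (SE 0.311) and Cd34 by 0.68 (SE 0.107). The median was 0.14 (adjusted p = 0.000154; adjusted p = 0.0660 with an estimated correlation), and 0.29, 0.19 and 0.16 within slides. Of 12 endothelial genes 2 rose (3 adjusted over the list alone), Flt1 and Pecam1, the latter by 0.67 (SE 0.115). The median was 0.28 (adjusted p = 0.000410; adjusted p = 0.0746 with an estimated correlation), and 0.61, 0.19 and 0.13 within slides. Of 20 hypoxia and glycolysis genes 3 rose (4 adjusted over the list alone, and 1 fell): Egln3 by 1.03 (SE 0.160), Ndrg1 by 0.60 (SE 0.0742) and Ddit4 by 0.34 (SE 0.0695). The hypoxia median was 0.12 (adjusted p = 0.000580; adjusted p = 0.214 with an estimated correlation), and 0.24, 0.21 and -0.03 within slides. Of 18 inflammatory genes 3 rose (5 adjusted over the list alone, and 2 fell): the cytokine Il1b by 1.74 (SE 0.255), the chemokine Cxcl3 by 1.03 (SE 0.129) and the acute-phase gene Saa3 by 0.54 (SE 0.102). The inflammatory median was 0.13 (adjusted p = 0.0130; adjusted p = 0.214 with an estimated correlation), and 0.17, 0.25 and 0.04 within slides. With slide as a block the medians of these 6 lists were 0.29, 0.26, 0.17, 0.25, 0.12 and 0.16, and all passed, but none did with an estimated correlation as well (adjusted p 0.0763 to 0.372). The endothelial median was 0.15 with the Cy5 signal alone and the progenitor median 0.24 with the software's log ratio. Without the 4 arrays of slide 1 the hypoxia list did not pass (median 0.05, adjusted p = 0.101), nor did Egln3 (0.96, 0.114), Il1b (1.56, 0.0543), Saa3 (0.39, 0.0973), Stard4 (0.67, 0.155) or Ddit4 (0.31, 0.177). Fewer arrays were then left, saline 2 and saline 3 against TPO 2, TPO 3 and TPO 4, so these losses need not come from slide 1 itself. Cxcl3 lay at 0.29 with the Cy5 signal alone (adjusted p = 0.898), where Pecam1, Egln3, Stard4 and Ddit4 also lost their calls, as did Saa3 and Stard4 with the software's log ratio. Stard4 lost its call without any of 9 of the 12 arrays (adjusted p 0.0522 to 0.117) and Ddit4 without TPO 1, TPO 4, saline 3 or saline 4 (0.0633 to 0.0804). Replicate number as a block also ended the call of Stard4 (adjusted p = 0.0575).

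The falls were smaller. Epas1, the hypoxia-inducible factor HIF-2alpha, fell by 0.59 (SE 0.101), the hydrolase Cmbl fell by 0.59 (SE 0.0707) and Lpl, lipoprotein lipase, fell by 0.52 (SE 0.0811). Cd109, a co-receptor that dampens TGF-beta signalling, fell by 0.49 (SE 0.106), the cholesterol exporter Abcg1 fell by 0.44 (SE 0.0900) and Inhbb, an activin subunit, fell by 0.41 (SE 0.0961). Cd109 lost its call without any of 5 arrays (saline 1, saline 4, TPO 1, TPO 3 or TPO 4; adjusted p 0.0595 to 0.0944), Abcg1 without saline 1, saline 3, saline 4, TPO 2 or TPO 4 (0.0635 to 0.0769) and Inhbb without any of 9 arrays (0.0610 to 0.149). All 3 also lost it without slide 1 (Cd109 at -0.35, adjusted p = 0.389; Abcg1 at -0.44, 0.204; Inhbb at -0.38, 0.158). With the Cy5 signal alone these 3, Epas1 and Lpl lost their calls, and with the mean over a gene's probes Cd109, Inhbb and Lpl did. Inhbb also lost its call with replicate number as a block (adjusted p = 0.0527). The bone genes did not pass: Alpl lay at -0.36 (adjusted p = 0.445), Sp7 at -0.29, Runx2 at -0.15, Bglap at -0.13, Spp1 at -0.11 and Col1a1 at -0.07. The BMP target genes did not pass either, with Id2 at -0.23, Id3 at -0.16, Smad6 at -0.06, Smad7 at 0.06 and Id1 at 0.01. Bmp2 lay at 0.65 (SE 0.234, adjusted p = 0.315) and passed with slide as a block (0.80, adjusted p = 0.0176). Osteoblast genes had a median of -0.12 (0 of 17 passed in limma, 0 adjusted over the list alone; camera adjusted p = 0.25), and -0.10 relative to the median of all genes both with loess and with median centring. BMP target genes had a median of -0.05 (0 of 20 passed, 0 adjusted over the list alone; camera adjusted p = 0.444), and -0.03 and -0.04 relative to it.

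With fry 10 lists passed, and with slide as a block 10, but 0 with slide as a block and an estimated correlation (lowest adjusted p = 0.0763). Without the 4 arrays of slide 1 the counts were 296 genes higher and 6 lower, of which 271 were among the 404. The software's log ratio gave 484 higher and 133 lower; median centring moved the median of all genes to 0.12 and gave 139 higher and 0 lower (488 genes at an unadjusted p under 0.05), 125 of them among the 404. Over the 3 comparisons, median centring ended 68 of the 107 gene calls followed and turned the sign of a further 3.

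**Figure D3:**
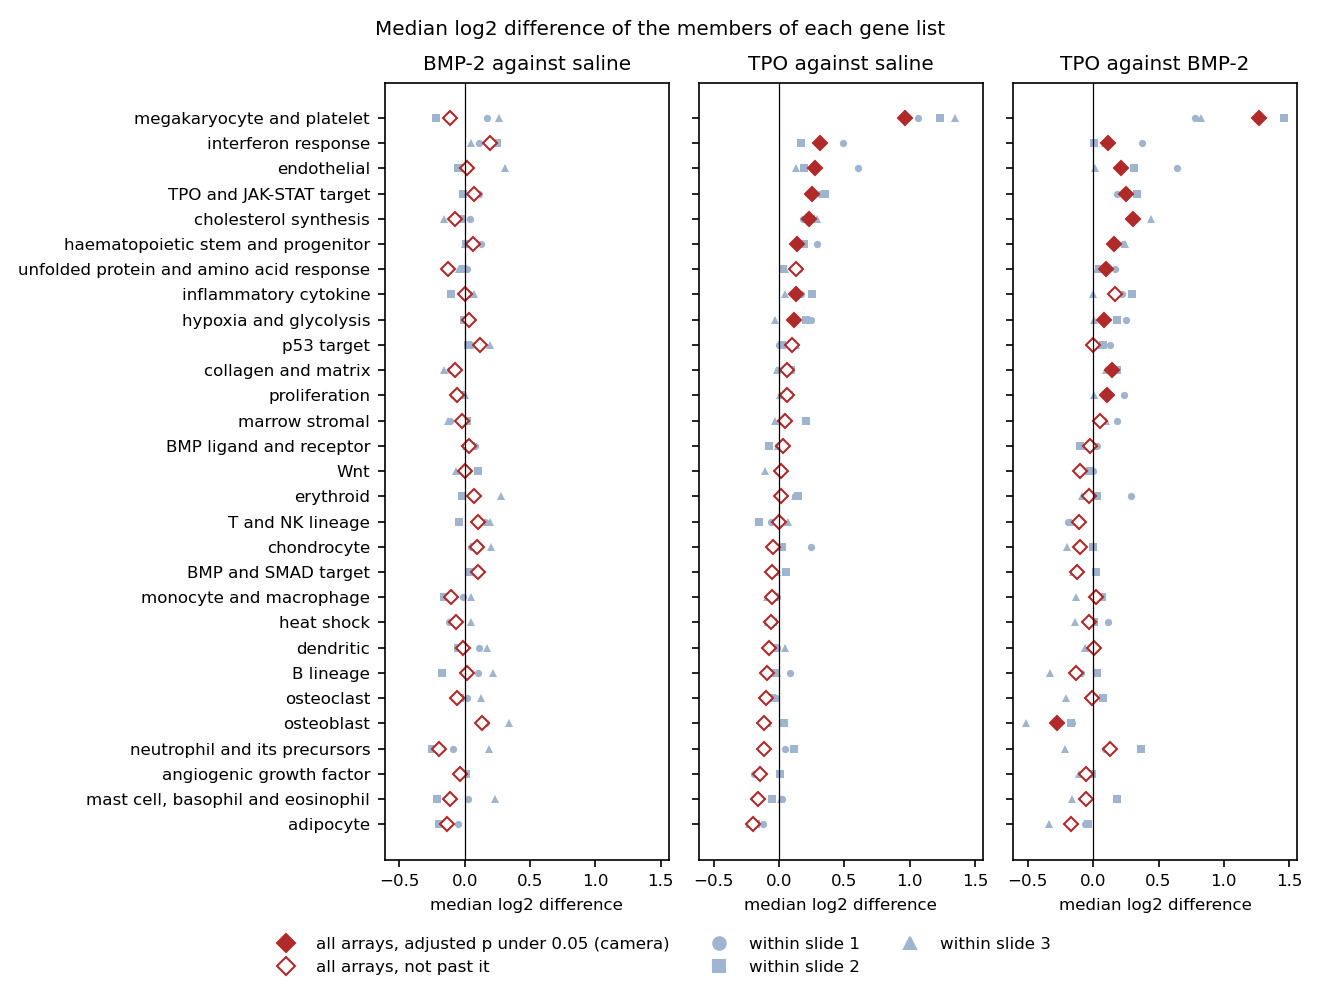
Median log2 difference (x axis) of the tested members of each of 29 gene lists (y axis) in the 3 comparisons; red diamonds give the value over all arrays, filled where camera with its preset correlation gave an adjusted p under 0.05, and pale symbols the values within each slide. Megakaryocyte and platelet genes lie at 0.96 for TPO against saline and 1.27 for TPO against BMP-2; with median centring, which moves the median of all genes to -0.32, 7 of the 11 filled medians for TPO against BMP-2 change sign, but relative to that median the hypoxia list alone does (-0.03).

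The comparison of TPO with BMP-2 sets the treatments against each other. A rise or fall in it is that of TPO relative to BMP-2. Such a difference does not tell which treatment moved the gene away from saline. Alpl was 4.61-fold lower with TPO (it fell by 2.20 on the log2 scale, SE 0.149, n = 4 per group, adjusted p = 2.57e-06), and Fmod fell by 1.31 (SE 0.175, adjusted p = 0.000862). Upward, Col18a1 was 7.74-fold higher (2.95, SE 0.161, adjusted p = 5.96e-07), F2r rose by 2.67 (SE 0.151), Flt1 by 2.48 (SE 0.150), Ehd3 by 2.28 (SE 0.0871) and Pf4 by 2.15 (SE 0.117). In all, 490 genes were higher with TPO and 263 lower, of which 140 and 4 differed more than 2-fold. A slide block gave 861 higher and 723 lower, 744 of the 753 genes being called in both fits. Of the 753, 719 (95.5%) differed in the same direction on all 3 slides, against 46.2% of all genes. Here too the genes were picked on these same arrays, so the agreement is no separate test.

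Among the genes lower with TPO were also Pdk4, a kinase that turns off pyruvate oxidation (fell by 1.14, SE 0.175), Whrn (fell by 0.84, SE 0.0883), the G-protein regulator Rgs16 (fell by 0.80, SE 0.112), Dlx2 (fell by 0.78, SE 0.117), the receptor Gprc5b (fell by 0.78, SE 0.0842), the Wnt co-receptor family member Lrp4 (fell by 0.74, SE 0.0910) and Ptgs2 (fell by 0.59, SE 0.0929). Dynap was at least 2.04-fold lower, being well above background on 0 of the 4 TPO arrays (adjusted p = 3.96e-05). Of 17 osteoblast genes 1 fell and 16 did not pass (6 fell adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.00873; adjusted p = 0.306 with an estimated correlation), and -0.16, -0.17 and -0.51 within slides. Sp7 lay at -1.11 (adjusted p = 0.154), Bglap at -0.58 (0.0739), Col1a1 at -0.36 (0.0543), Spp1 at -0.33 (0.196) and Runx2 at -0.27 (0.0701). With slide as a block, Sp7 (0.00546), Bglap (0.0363), Col1a1 (0.0361) and Runx2 (0.0493) passed. Of the BMP targets, Id2 fell by 0.37 (SE 0.0947, adjusted p = 0.0443) but lost its call without any of 10 of the 12 arrays (adjusted p 0.0570 to 0.146). Id2 also lost it with the Cy5 signal alone and the mean over a gene's probes. Smad6 lay at -0.47 (0.0667; -0.44 and 0.0228 with slide as a block), Smad7 at -0.33 (0.0946), Id1 at -0.19 (0.355) and Id3 at 0.27 (0.275). Bmpr2, a BMP receptor, fell by 0.33 (SE 0.0745) but lost its call without any of 7 of the arrays (adjusted p 0.0511 to 0.0900) and under the same 2 alternatives as Id2. Bmp2 lay at 0.75 (adjusted p = 0.0830) and passed with slide as a block (0.77, adjusted p = 0.0152). Dlx2 lost its call with the Cy5 signal alone (-0.63, adjusted p = 0.206). The osteoblast median was -0.47 with the software's log ratio.

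Of the 33 megakaryocyte and platelet genes, 17 rose, 16 did not pass and all 33 lay higher; 32 rose adjusted over the list alone. The median was 1.27 (adjusted p = 1.79e-25; adjusted p = 0.152 with an estimated correlation), and 0.78, 1.46 and 0.83 within slides; it was 0.52 with the software's log ratio. Cavin2 rose by 1.64 (SE 0.101), Zfpm1 by 1.40 (SE 0.102), Thbs1 by 1.27 (SE 0.147), Gata1 by 0.91 (SE 0.195) and Itga2b by 1.51 (SE 0.379, adjusted p = 0.0406). Gata1 lost its call without TPO 2 or BMP-2 3 (adjusted p 0.0515 to 0.0611), Itga2b without any of 8 of the 12 arrays (0.0552 to 0.128), and Trpc6, a calcium channel of platelets that rose by 2.09 (SE 0.552, adjusted p = 0.0498), without any of 11 (0.0505 to 0.130). With the software's log ratio Gata1 (0.37, adjusted p = 0.264), Trpc6 (1.55, 0.191) and Hemgn (2.07, 0.185) lost theirs. Mpl lay at 0.75 (adjusted p = 0.102) and passed with slide as a block (0.73, adjusted p = 0.0148) and with the Cy5 signal alone (1.34, adjusted p = 7.63e-06). Thpo lay at -0.15. Further rises were those of Clca3a1 (2.46, SE 0.348), Hemgn (2.38, SE 0.314), Gsta1 (2.32, SE 0.212), Mylk (2.05, SE 0.0792), the erythroid genes Car2 (1.24, SE 0.160) and Epor (0.86, SE 0.172) and the matrix proteoglycan Dcn (0.93, SE 0.146).

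The other lists that passed were upward over all arrays, and the sign of 7 of them turned with median centring, under which the median of all genes was -0.32. Relative to that median, the 7 stayed positive except hypoxia (-0.03). The TPO and JAK-STAT targets (4 of 18 rose, with 8 higher and 2 lower adjusted over the list alone; median 0.25, adjusted p = 0.00126; adjusted p = 0.152 with an estimated correlation) turned to -0.10 there. Cish rose by 1.06 (SE 0.171), Ccnd3 by 0.78, Ccnd2 by 0.77 and Socs3 by 0.45 (SE 0.0852), the last at -0.0046 with median centring. Cholesterol synthesis genes (7 of 18 rose, with 10 higher and 1 lower adjusted over the list alone; median 0.30, adjusted p = 4.59e-08; adjusted p = 0.0652 with an estimated correlation) turned to -0.01. Stard4 rose by 0.97 (SE 0.127), the rate-limiting enzyme Hmgcr by 0.79 (SE 0.127), Dhcr24 by 0.75 and Idi1 by 0.75. Collagen and matrix genes (3 of 25 rose and 1 fell, 4 and 2 adjusted over the list alone; median 0.14, adjusted p = 0.00873; adjusted p = 0.255 with an estimated correlation) turned to -0.26. In this list Timp3, a metalloproteinase inhibitor, rose by 1.13 (SE 0.0847), as it did by 0.98 (SE 0.0847) against saline. Thbs1, which is on the megakaryocyte and platelet list too, also rose. Fibronectin, Fn1, was higher by 0.36 (SE 0.0935, -0.06 with median centring). Its TPO arrays (-2.33 to -1.98) overlapped the saline ones (-2.25 to -2.05), and its BMP-2 arrays lay lower (-2.63 to -2.34). Postn, a matrix protein of bone-lining tissue, fell by 0.58 (SE 0.118). Hypoxia genes (4 of 20 rose, with 5 higher and 1 lower adjusted over the list alone; median 0.08, adjusted p = 0.00873; adjusted p = 0.306 with an estimated correlation) turned to -0.35. Eno1 rose by 0.86 (SE 0.174), Egln3 by 0.82 (SE 0.160) and Ndrg1 by 0.58. Interferon genes (1 of 19 rose, also 1 adjusted over the list alone: Isg15, by 1.07; median 0.11, adjusted p = 0.0112; adjusted p = 0.341 with an estimated correlation) turned to -0.21. Proliferation genes (1 of 31 rose, also 1 adjusted over the list alone: Cdc20, by 0.49; median 0.11, adjusted p = 0.00873; adjusted p = 0.426 with an estimated correlation) turned to -0.30. Unfolded protein genes (2 of 15 rose, 4 adjusted over the list alone; median 0.10, adjusted p = 0.0375; adjusted p = 0.181 with an estimated correlation) turned to -0.29. Pdia4 rose by 1.06 (SE 0.234) and Atf4 by 0.38 (SE 0.0971, -0.06 with median centring). Within slides these medians were 0.18, 0.33 and 0.25 for the TPO targets, 0.30, 0.31 and 0.45 for cholesterol synthesis, 0.12, 0.18 and 0.10 for collagen, 0.25, 0.18 and 0.01 for hypoxia, 0.37, 0.01 and 0.09 for interferon, 0.24, 0.10 and 0.01 for proliferation and 0.16, 0.05 and 0.03 for unfolded protein genes. Calls were lost without single arrays for Pdia4 (TPO 2, TPO 3, BMP-2 3 or BMP-2 4; adjusted p 0.0650 to 0.0780), Eno1 (TPO 3 or BMP-2 3; 0.0551 to 0.0607), Postn (TPO 2 or BMP-2 3; 0.0515 to 0.0589), Fn1 (any of 9; 0.0543 to 0.136) and Atf4 (any of 10; 0.0536 to 0.152). Egln3, Postn, Fn1 and Atf4 also lost theirs with the Cy5 signal alone, Atf4 with the software's log ratio, and Fn1 with the mean over a gene's probes and without slide 1 (0.27, adjusted p = 0.0910). Replicate number as a block also ended the call of Fn1 (adjusted p = 0.0537). The collagen, hypoxia and proliferation medians were 0.09, 0.03 and 0.05 with the Cy5 signal alone.

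Stem and progenitor genes (3 of 17 rose and 1 fell, 5 and 1 adjusted over the list alone; median 0.16, adjusted p = 0.00873; adjusted p = 0.181 with an estimated correlation) and endothelial genes (2 of 12 rose, 3 adjusted over the list alone; median 0.21, adjusted p = 0.00873; adjusted p = 0.181 with an estimated correlation) kept their sign with median centring, as did the megakaryocyte (0.89) and osteoblast (-0.54) lists. Slamf1 rose by 1.79 (SE 0.311), Cd34 by 0.61 (SE 0.107) and Pecam1 by 0.74 (SE 0.115). Within slides the medians were 0.23, 0.15 and 0.25 for the progenitor list and 0.64, 0.31 and 0.02 for the endothelial list; they were 0.31 with the software's log ratio and 0.05 with the Cy5 signal alone. Of 18 inflammatory genes 3 rose and 1 fell (5 and 3 adjusted over the list alone), Il1b by 1.49 (SE 0.255), Cxcl3 by 0.99 (SE 0.129; 0.52, adjusted p = 0.18 with the Cy5 signal alone) and Saa3 by 0.70 (SE 0.102), but the list did not pass (median 0.16, adjusted p = 0.0584; with median centring -0.15, or 0.17 relative to the median of all genes). It passed with slide as a block (median 0.21, adjusted p = 0.0289; adjusted p = 0.335 with an estimated correlation).

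Of the 11 lists, 0 passed with an estimated correlation (6 at an unadjusted p under 0.05 in camera) and 10 of the 29 lists passed with fry, where interferon (adjusted p = 0.0526) and proliferation (0.157) did not. With slide as a block the unfolded protein list did not pass (median 0.09, adjusted p = 0.0613). The other 10 did, with medians of 1.21 for megakaryocyte, 0.29 for cholesterol, 0.23 for TPO target, 0.27 for endothelial, 0.09 for hypoxia, 0.18 for progenitor, 0.13 for proliferation, 0.13 for collagen, -0.24 for osteoblast and 0.12 for interferon genes. None of them passed with an estimated correlation as well (adjusted p 0.0602 to 0.426). Without BMP-2 1, 7 lists passed: collagen (median 0.08, adjusted p = 0.0950), interferon (0.04, 0.125), proliferation (0.04, 0.170) and unfolded protein genes (0.05, 0.109) did not. Interferon also did not pass without TPO 1 (0.07, 0.0737), nor did unfolded protein genes without TPO 3 (0.10, 0.0640) or TPO 4 (0.09, 0.0514). Without the 4 arrays of slide 1, 6 lists passed, and the endothelial (0.07), hypoxia (0.07), interferon (-0.01), proliferation (-0.01) and unfolded protein lists (0.04) did not. The gene count was 1425 without BMP-2 1, 1644 (811 higher, 833 lower) without the slide 1 arrays, 474 without BMP-2 4, 460 without TPO 4, 410 without TPO 2, 395 without TPO 3 and 349 without BMP-2 3. The split of 490 higher and 263 lower became 844 and 1538 with the software's log ratio, 586 and 481 with no background correction and 45 and 3 with median centring.

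BMP-2 and TPO shared 1 gene among those they raised against saline, Serpinb2, which TPO raised by 1.27 (SE 0.137, adjusted p = 0.000116); it is named here because it was the shared gene. The overlap rests on single arrays: it was 0 without any of 10 of the 12 arrays, where Serpinb2 lost its call for BMP-2 (adjusted p 0.0633 to 0.199), and 0 without the 4 arrays of slide 1. Independent lists of those sizes would share 0.142 genes, and unchanged groups simulated against the same saline arrays shared 0. No gene fell in both (0 in limma, since 0 fell with BMP-2). Across genes, which are not independent replicates, the log2 changes of both treatments against saline correlated at 0.179, where 100 simulations of unchanged groups against those arrays gave a mean of 0.502. Their covariance was 0.00834 against a simulated 0.0110 (difference -0.00263). With the saline arrays split into separate pairs, the correlation ran from -0.26 to 0.20 over 6 splits, and no gene was shared (0).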

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

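The tests of slide shares, of cell makeup and of the osteoblast and stromal genes were chosen after the results were seen, as were the spreads given with the tests of slide 1; the other tests were set beforehand. In 282 groups of 4 arrays (87 genes and 7 array measures), 9 held an array far from the other 3, where chance gives about 1 in 20.

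The Cy3 signal of BMP-2 2 was above background for 67.9% of probes, against at most 58.3% on the other BMP-2 arrays. BMP-2 1 had 487 outlier spots, against at most 195. Fmod lay at -1.11 on saline 4, against -0.69 on the nearest other saline array. Runx2 lay at -0.78 on saline 2, against -0.89. Stard4 lay at 0.40 on saline 2, against 0.64. Mylk lay at -1.36 on BMP-2 4, against -1.56, Car2 at 0.35 on BMP-2 4, against 0.65, and Bbc3 at -5.11e-05 on BMP-2 4, against 0.25. Epor lay at 3.27 on TPO 1, against 2.67.

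The arrays of slide 1, which hold all 3 treatments, stand apart on the first principal component. After loess and Aquantile normalization, which use Cy5 and Cy3 together, the reference channel carried a share of 0.0416 of the slide 1 effect. This argues against it as the source. A difference in scale between slides stays open: the mean log ratio of a gene explained 22.6% of the effect's variance, but 18.8% to 25.3% with 1 array left out, which spans the bound of 25% set beforehand. Another cell makeup of the cultures on slide 1 cannot be told apart from other causes: the lowest median of the myeloid and megakaryocytic lists minus the highest of the stromal ones was -0.196, with 95% of resamplings from -0.402 to 0.129.

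Megakaryocyte and platelet genes were higher with TPO than with saline. An unequal share of the slides is argued against by the medians within slides, of which the lowest was 1.06. The reference channel is argued against by a median difference of 0.534 in Cy3, since a rise there lowers the ratio. The Cy3 values were taken after loess and Aquantile normalization. These steps use Cy5 and Cy3 together, so the values are not free of the Cy5 signal. Cy3 held the same reference RNA on every array, so the rise is itself unexplained, and its cause was not tested. Chance is argued against but not excluded. Of the 35 splits of the 8 arrays, 1, the real one, gave a median as far from 0 (0.96, highest other 0.852). That is the lowest share that 35 splits can give. A larger share of megakaryocytes cannot be told apart from more transcription per cell, since all 33 members were higher, as either would give, and cells were not counted in these data.

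The 5 genes higher with BMP-2 than with saline include 1 bone gene, Alpl. Within slides the lowest median of the 5 genes was 0.725 and the highest 1.00. Because the 5 were picked on these same arrays, this does not test an unequal share of the slides. The reference channel is argued against by a Cy3 difference of 0.000625, taken after loess and Aquantile normalization, which use Cy5 and Cy3 together. A larger share of stromal cells is argued against by the 40 stromal and collagen genes outside the osteoblast list, whose median was -0.0459 (quartiles -0.257 and 0.0496). A larger share of osteoblasts cannot be told apart from more transcription per cell: the other 16 osteoblast genes had a median of 0.126, but quartiles of -0.0167 and 0.447, with 12 higher. The splits do not argue against chance for the count: 2 of the 35 gave as many genes in limma. The other, saline 1, saline 3, saline 4 and BMP-2 1 against the rest, called 1685. It exchanges saline 2 and BMP-2 1 in the real split, and so puts all slide 1 arrays on 1 side. The 4 further splits with these arrays on 1 side called 0 each, and why this split called 1685 was not tested. Among the splits that divide the slide 1 arrays, the real one alone called any gene. With slide as a block the real split called 9.

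For the gene counts of both TPO comparisons chance is argued against but not excluded, since 1 of 35 is the lowest share these splits can give. The real split alone gave as many for TPO against saline (1 of the 35 splits, real 404, highest other 0). The same held for TPO against BMP-2 (1 of the 35, real 753, highest other 0). The splits do not argue against chance for the lists. There 7 of the 35 splits gave as many for TPO against saline (real 8, highest other 12) and 8 for TPO against BMP-2 (real 11, highest other 20). For the lists of BMP-2 against saline the splits decide nothing: the real count is 0, so 35 of the 35 give as many whatever the data (highest other 13).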

How the results depend on the processing

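Leaving out the 4 arrays of slide 1, and slide as a block with array weights, were chosen after the data were seen, as were all settings of the shared genes but 4 (saline split, median centring, slide and replicate blocks); the others were planned. Of 4363 alternatives run for the 158 named gene results, 3956 kept direction and side of the threshold, 296 lost a call, 108 gained one and 3 reversed; of 361 for the 19 lists that passed, 327 kept both and 34 lost the call. Sign changes of values that passed in neither setting count as kept. Of 107 gene calls, 30 held under all the alternatives run. Median centring ended 68 calls and reversed Socs3 (-0.0046), Atf4 (-0.059) and Fn1 (-0.063) for TPO against BMP-2, where it moved the median of all genes to -0.32. Aquantile normalization moved no ratio, by construction.

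The genes changed were 5, 404 and 753 for BMP-2 against saline, TPO against saline and TPO against BMP-2. They became 10 for the first with no background correction, 14, 617 and 2382 with the software's log ratio, 14, 617 and 2369 with the series value table, 1, 139 and 48 with median centring, 9, 630 and 1584 with slide as a block, and 75, 905 and 2249 with slide as a block and array weights. They were 10 for the first and 2156 for the third with array weights. With probes above background in both channels on all arrays (9011 genes tested) they were 3 and 1177, and without slide 1 they were 1 and 1644. The third was 497 with the Cy5 signal alone and 437 with only the groups compared. Leaving out 1 array each gave 2 to 7, 304 to 450 and 349 to 1425. The first was 2 without saline 1, saline 4 or BMP-2 3, and the third 1425 without BMP-2 1, 474 without BMP-2 4, 460 without TPO 4, 410 without TPO 2, 395 without TPO 3 and 349 without BMP-2 3. Replicate number as a block gave 5, 458 and 963. Whether the numbers pair the arrays cannot be told, since 9 of the 12 same-number pairs also share a slide. Of 12 arrays, 6 correlated best with their own number, and same-number correlations ran from -0.499 to 0.71. The 3 same-number pairs on different slides had a median of -0.461 (-0.499 to 0.452). The 6 different-number pairs on the same slide had a median of 0.53 (0.164 to 0.698).

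The lists that passed were 0, 8 and 11. For BMP-2 against saline they became 3 with slide as a block, 1 with replicate number as a block and 5 with the mean over a gene's probes. With an estimated correlation they became 1 for TPO against saline and 0 for TPO against BMP-2 (6 at an unadjusted p under 0.05), and without slide 1 the latter were 6. Leaving out 1 array gave 0 to 5, 8 to 10 and 7 to 12. The 1 shared gene became 0 with the saline arrays split, with median centring, with either other filter on dim probes, with only the groups compared, without slide 1 and without any of 10 of the 12 arrays (not saline 2 or BMP-2 4), and 8 with slide as a block and array weights. The cause was not tested where none is named. Signal limits the tested genes: Cy5 was above background for 37.4% to 67.7% of probes.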

Other observations

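The values here come from lists and comparisons fixed before the data were examined; the slide 1 values were looked at after the result was seen. With TPO, genes of red cells, bone-resorbing cells and vessel growth rose singly while their lists did not pass over all arrays. Car2, the carbonic anhydrase of red cells and osteoclasts, rose by 1.51 (SE 0.160, n = 4 per group) against saline, and Epor, the erythropoietin receptor, by 0.96 (SE 0.172). Of 10 erythroid genes 2 rose (3 adjusted over the list alone; median 0.01, camera adjusted p = 0.0774). With slide as a block the erythroid list passed (median 0.05, adjusted p = 0.0122; adjusted p = 0.382 with an estimated correlation). Against BMP-2 3 rose, with a median of -0.03, a mean of 0.27 and an upward test (adjusted p = 0.174). The kinase Src, needed by osteoclasts, rose by 0.80 (SE 0.106) and the integrin Itgb3, of platelets and osteoclasts, by 0.54 (SE 0.118), while the 15 osteoclast genes had a median of -0.10 (adjusted p = 0.809; relative to the median of all genes -0.08, and -0.09 with median centring). The vessel growth factors Angpt1 and Vegfc rose by 0.58 (SE 0.132) and 0.54 (SE 0.122). Angpt1 lost its call without any of 7 of the 12 arrays (adjusted p 0.0606 to 0.127) and Vegfc without any of 8 (0.0572 to 0.137). Both also lost it without the 4 arrays of slide 1 (Angpt1 at 0.28, adjusted p = 0.326; Vegfc at 0.45, 0.0907) and with the Cy5 signal alone (0.36, 0.889; 0.54, 0.0918), and Angpt1 with the software's log ratio (1.17, 0.0954).

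The p53 targets Cdkn1a, a brake on the cell cycle, and Bbc3, a promoter of cell death, rose by 0.67 (SE 0.0945) and 0.61 (SE 0.105) with TPO against saline. Bbc3 lost its call without the 4 arrays of slide 1 (0.58, adjusted p = 0.0644). The list of 11 came near the threshold (median 0.10, adjusted p = 0.0513) and passed with fry (adjusted p = 0.0117), but lay farther from it with slide as a block (adjusted p = 0.14; adjusted p = 0.214 with an estimated correlation and no block). Within slides its median was -0.0010, 0.03 and 0.13. Of 7 adipocyte genes 1 fell, Lpl (not with the Cy5 signal alone), and the list had a median of -0.20 (adjusted p = 0.0669, or 0.214 with an estimated correlation; 0.0317 with slide as a block, or 0.459 with both). Lists of white cells did not pass, with medians of -0.12 for neutrophil, -0.06 for monocyte, -0.07 for dendritic, -0.16 for mast cell, -0.09 for B lineage and 0.00 for T and NK genes. Those for stromal, chondrocyte, Wnt, BMP ligand, angiogenic and heat shock genes were 0.05, -0.05, 0.01, 0.03, -0.15 and -0.06. In the slide 1 effect the osteoclast list lay at 0.31, the B lineage list at 0.29, the proliferation list at -0.12 and the T and NK list at -0.16, and 213 genes differed by more than 1 in log2 size.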
